A study of Homo sapiens with 28 samples.

How the data were processed

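The series holds 28 samples of Fucci human embryonic stem cells grown in a defined medium without serum or feeder cells: 16 ChIP libraries (4 marks in 4 sorted fractions), 4 inputs and 8 4C libraries (2 viewpoints in 4 fractions). Groups were taken from the labels, with 1 library in each. Nuclei for 4C were cut with HindIII, ligated, cut again with NlaIII and ligated again before amplification, per the labels' protocols. Bowtie 0.12.7 and the builds hg19 and mm9 are named, without a role, per the submitters' processing notes. Positions in the peak lists and the 4C table lie on human chromosomes, and coordinates are given as deposited and read as hg19. The peak caller, its settings, any use of the inputs and the filters on reads are not given in the sources used here. The inputs were not analysed here.

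Each ChIP file was a list of peaks called for 1 library. The deposited signal column, used as the peak height, is not a whole number, and its scaling is not given in the sources used here. The deposited score column was negative in every list and more negative for taller peaks. That the first is a maximum height and the second a log score was read from the values. Both are the authors' values. All peaks began and ended on a 25 bp grid. Every peak on the chromosomes coded 22 to 24, and a few others, had a height of 0, which was treated as missing, so height comparisons cover chromosomes 1 to 21. The deposited 4C table gave counts, whole-number reads per restriction site for 837622 sites, and how reads were assigned to sites is not given in the sources used here. No per-sample column was left unused.

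Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. Peaks were called shared when they overlapped by at least 1 bp. Shares carry exact Clopper-Pearson 95% intervals, which treat peaks or reads as independent and cover counting error only; 4C reads are PCR products without molecular identifiers. No p-value was computed.

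Promoter and gene-list comparisons were planned before the data were examined, with 14 gene lists of 320 genes, but no annotation of hg19 was at hand, so none of the lists was tested. H3K4me3 peaks of the 4 fractions were merged into 32799 regions that stand in for promoters, a region was bivalent when peaks of both marks overlapped it in 1 fraction, and distance from these regions stood in for distance from a transcription start. In place of gene lists, 2 classes of regions on chromosomes 1 to 21 were compared: bivalent in all fractions, and H3K4me3 in all fractions with H3K27me3 in none. These substitutes were chosen after the files were seen. Relative height is the tallest peak of a region divided by the library's median over regions marked in all fractions. The median log2 ratio of a class was placed among 10000 random lists, each drawing for every member 1 of the 20 H3K4me3-only regions nearest in mean height. Tested on simulated data (40 lists of 800 among 8000 regions), 85% of lists without a shift fell between percentiles 2.5 and 97.5, so the percentiles are too extreme and serve as descriptions; 100% of lists with a shift of 0.15 (log2) lay above percentile 97.5.

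For 4C, the labels do not give the viewpoint's coordinate, and the site with the most reads, the same in all 4 libraries of a viewpoint, was used. Sites within 10 kb of it were left out, and the shares of cis reads within 100 kb, beyond 1 Mb and beyond 10 Mb were computed; the last distance was added after the data were seen. Contact windows were the 20 windows of 50 kb with the most reads within 5 Mb, set against 10000 random sets drawn from the same distance classes. Gene order around GATA6 and SOX17 came from a RefSeq table of the GRCh38 assembly, used for names and order alone.

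Regions named in the text followed a rule fixed beforehand, applied to coordinates: for each step of the cycle up to 3 gained and 3 lost peaks by height, 5 for H3K4me3 gained from early to late G1, the 3 largest and 3 smallest ratios of relative H3K4me3 height, up to 8 regions entering and 8 leaving the bivalent set, and the 5 windows with the most 4C reads. The text gives a part of them. Alternatives were stricter lists (the upper part by score, or equal numbers per fraction), peaks of at least 500 bp, coverage of at least 50% of a peak, H3K27me3 within 500 or 2500 bp, heights as deposited (where the library's constant cancels from the class difference) and ranks, a 10 kb distal limit, 2 or 50 kb left out around the viewpoint, sites counted once, the tallest site left out, 20 and 100 kb windows, and 50 contact windows. Added after the data were seen were scores in place of heights and the removal of 655 regions where H3K27me3 and H3K27ac peaks overlapped.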

Results

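Human embryonic stem cells that carry the Fucci reporters, fluorescent proteins whose abundance follows the cell cycle, were sorted into 4 fractions: early G1, late G1, S phase and G2/M. Each fraction was profiled by ChIP-seq for 4 histone marks, giving 16 peak lists, and by 4C-seq from 2 viewpoints beside the GATA6 and SOX17 promoters, giving 8 libraries. GATA6 and SOX17 encode transcription factors of endoderm. H3K4me3 marks active and poised promoters, H3K27me3 marks Polycomb-repressed chromatin, H3K27ac marks active promoters and enhancers, and H3K4me1 marks enhancers. The 4 input libraries were not analysed here. Every mark and viewpoint had 1 library per fraction, so there are no replicates, no test between fractions was possible, and the exact binomial intervals given cover counting error only. The number of reads behind each ChIP list is unknown here. The 4C libraries held 13936585, 12974772, 8905806 and 17076409 reads for GATA6 and 10719725, 10675688, 7491195 and 15566252 reads for SOX17, in the order early G1, late G1, S and G2/M, an order kept below wherever 4 values are given together.

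H3K4me3 had the largest share of merged regions listed in all 4 fractions among the marks. The lists held 24757, 25653, 25977 and 28735 peaks, and 15661 of the 32799 merged H3K4me3 regions (47.7%) carried a peak in all 4 fractions. Of the late G1 peaks, 81.1% overlapped an early G1 peak (95% interval 80.6 to 81.6) and 84.9% an S-phase peak (84.5 to 85.4). Of the S-phase peaks, 79.7% overlapped a G2/M peak (79.2 to 80.2), and of the G2/M peaks, 77.4% an early G1 peak (76.9 to 77.9). Late G1 peaks without an early G1 partner were short, with a median of 175 bp against 675 bp for those with one. The total length covered was 22.2, 19.2, 22.01 and 19.7 Mb.

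The 5 tallest H3K4me3 peaks present in late G1 and missing from early G1 all also carried H3K27me3 and H3K27ac peaks in late G1. They lay at chromosome 5 from 9801 to 12000, chromosome 12 from 133841301 to 133842075, chromosome 2 from 33141051 to 33141750, chromosome 8 from 28258751 to 28259400 and chromosome 1 from 9826 to 10625, with heights of 467, 401, 339, 306 and 305. The place on chromosome 2 was listed for H3K4me1 too. In late G1, 1.24% of H3K27me3 peaks overlapped H3K27ac. Places listed for both may carry peaks whatever the mark, so they are not read as gains of H3K4me3 itself. The tallest early G1 peaks missing from late G1 lay at chromosome 19 from 36821576 to 36822725 (height 166), chromosome 3 from 44770926 to 44771675 (145) and chromosome 1 from 195815776 to 195817325 (127). None of these 3 carried H3K27me3, and those on chromosomes 19 and 1 carried H3K27ac in early G1. From late G1 to S, the tallest peaks no longer listed were 3 neighbours on chromosome 16, from 46397776 to 46401300 (height 140), from 46386676 to 46389025 (102) and from 46389101 to 46390175 (97.9). The tallest peak listed in S and not in late G1 lay at chromosome 1 from 36689151 to 36689675 (58.3) and carried H3K27ac. From S to G2/M the tallest addition was at chromosome 6 from 86159551 to 86160150 (164), and from G2/M to early G1 it was at chromosome 19 from 12162776 to 12163775 (96.3). The G2/M peaks missing from early G1 were taller, at chromosome 8 from 28258676 to 28259400 (539), chromosome 5 from 9801 to 12000 (528) and chromosome 10 from 103590251 to 103590875 (456), the first 2 also with H3K27me3 and H3K27ac.

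The length covered by H3K27me3 peaks was greatest in late G1 and smallest in S phase. The lists held 23755, 31682, 19989 and 26480 peaks covering 27.02, 32.0, 17.2 and 24.3 Mb, and domains of at least 5 kb numbered 907, 1100, 523 and 854. These domains held 37.0%, 39.3%, 34.0% and 39.7% of the covered length, and the median peak was 350, 300, 275 and 275 bp long. The S-phase list lay largely inside the others: 93.1% of its peaks overlapped a late G1 peak (92.7 to 93.4) and 83.1% an early G1 peak (82.6 to 83.7). In the other direction, 30.4% of late G1 peaks overlapped an S-phase peak (29.9 to 30.9) and 51.5% an early G1 peak (50.9 to 52.1). Peaks in all 4 fractions made up 6551 of 36340 merged regions (18.03%), and 11031 regions were listed in late G1 alone. Late G1 peaks with an S-phase partner had a median length of 1400 bp, those without one 225 bp.

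Among single H3K27me3 regions, the tallest listed in late G1 and not in early G1 lay at chromosome 10 from 42598851 to 42600650 (height 279), chromosome 2 from 33141076 to 33141725 (273) and chromosome 10 from 42596526 to 42598525 (252), and all 3 carried H3K4me3 as well. The one on chromosome 2 was also listed for H3K27ac and H3K4me1, so it may carry peaks whatever the mark. From late G1 to S the additions were chromosome 1 from 564476 to 566200 (128), chromosome 5 from 134263326 to 134263700 (103) and chromosome 1 from 568826 to 570175 (70.7), again all with H3K4me3. The tallest G2/M peaks missing from early G1 lay at chromosome 5 from 9801 to 11975 (365) and chromosome 10 from 42596526 to 42600675 (358) and from 42382776 to 42389825 (336), each with H3K4me3. The one on chromosome 5 was listed for H3K27ac too. Whether the regions named here carry peaks whatever the mark was not tested one by one. Several of the regions that the height rule picked on chromosome 20 had a tall height beside a weak score, such as 591701 to 591825 in early G1 with height 124 and score -0.663, and are not described further.

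H3K27ac was listed most widely in G1 and least in S phase. The lists held 30168, 32521, 10268 and 19525 peaks covering 9.94, 9.44, 2.53 and 5.60 Mb, so that the S-phase list had 0.316 times as many peaks as late G1 and G2/M had 1.90 times as many as S. The share of H3K4me3 peaks that overlapped H3K27ac was 34.1% in early G1 (33.5 to 34.7), 20.2% in late G1 (19.7 to 20.7), 5.82% in S (5.54 to 6.11) and 11.3% in G2/M (10.9 to 11.6). Early and late G1 had similar numbers of H3K27ac peaks, yet 40.5% of the early G1 peaks overlapped H3K4me3 (39.9 to 41.0) against 21.6% in late G1 (21.2 to 22.1). Of late G1 H3K27ac peaks, 49.5% overlapped an early G1 peak (49.0 to 50.1) and 23.1% an S-phase peak (22.6 to 23.6). Of S-phase peaks, 81.9% overlapped a late G1 peak (81.1 to 82.6). The 95th percentile of H3K27ac height was 2.60, 2.33, 2.30 and 2.38 times the 5th, against 11.7 to 20.2 times for H3K4me3. Most H3K27ac peaks thus stood close to the lowest heights listed. List length, sharing and overlap with H3K4me3 may therefore depend on the strength of each library, and these contrasts need not mean that the mark differs between fractions.

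The tallest H3K27ac peak listed in late G1 and not in early G1 lay at chromosome 10 from 134386276 to 134388150 (height 118), with H3K4me1 and without H3K4me3. Next came chromosome 13 from 113527076 to 113527825 (111) and chromosome 13 from 112732926 to 112733550 (99.5), the latter also listed for H3K27me3 and H3K4me1. The 3 tallest early G1 peaks missing from late G1 all carried H3K4me3, at chromosome 3 from 119814051 to 119814475 (75.8), chromosome 10 from 28821626 to 28821950 (72.0) and chromosome 7 from 26240626 to 26241050 (71.0). From late G1 to S the tallest loss was chromosome 17 from 41400151 to 41401200 (85.4). The tallest S-phase addition, chromosome 1 from 121483951 to 121485600 (273), was listed for all 4 marks. From S to G2/M the tallest addition was chromosome 2 from 232479251 to 232479775 (128), with H3K4me3. The tallest G2/M peak missing from early G1 was chromosome 1 from 121483926 to 121485600 (311), listed for all 4 marks. Those of the places named here that were also listed for H3K27me3 may carry peaks whatever the mark, so they are not read as gains of H3K27ac itself.

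**Figure D1:**
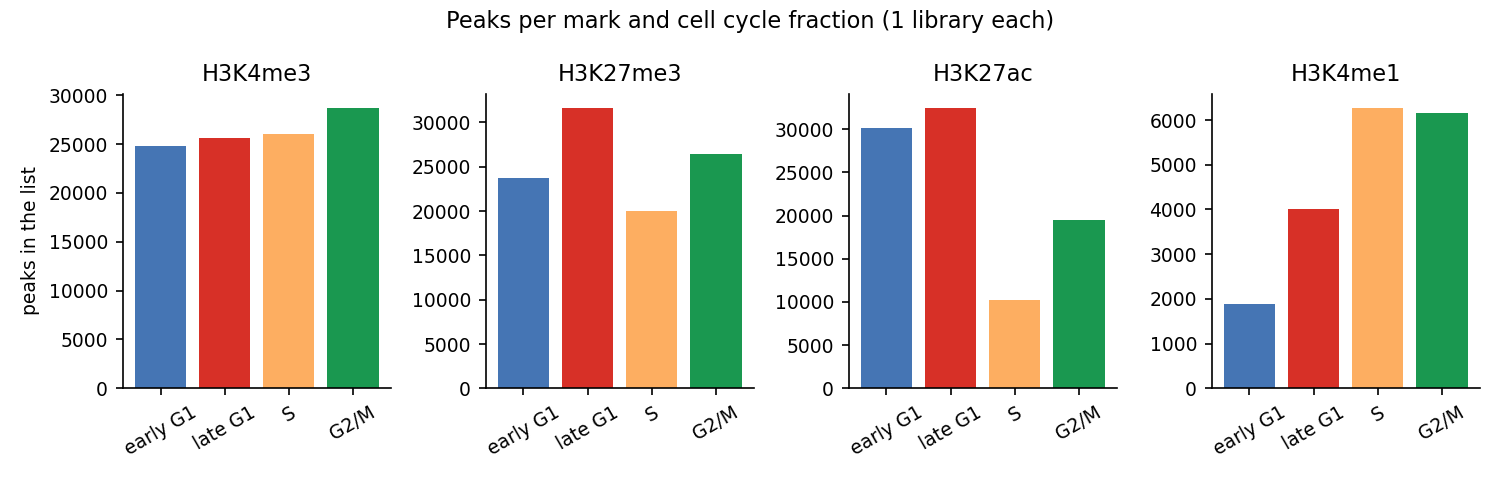
Number of peaks (vertical axis, a separate scale for each mark) in the 4 sorted fractions, 1 library per bar. H3K27ac had 32521 peaks in late G1 and 10268 in S, H3K27me3 had 31682 and 19989, and H3K4me1 had 1878 in early G1 and 6280 in S.

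H3K4me1 peaks were few and seldom shared. The lists held 1878, 4017, 6280 and 6156 peaks, all with a median length of 125 bp, and 45 of 16001 merged regions (0.281%) were listed in all 4 fractions. Of late G1 peaks, 3.24% overlapped an early G1 peak (2.71 to 3.83) and 14.7% an S-phase peak (13.7 to 15.9). The 95th percentile of H3K4me1 height was 1.40, 1.48, 1.60 and 1.62 times the 5th, against 11.7 to 20.2 times for H3K4me3. Most H3K4me1 peaks thus stood near the lowest heights listed, so scarce sharing need not mean that the mark differs between fractions. Peaks more than 2.5 kb from any H3K4me3 region, called distal here, numbered 1555, 3370, 5137 and 5241. H3K27ac was present at 29.3% of the distal H3K4me1 peaks in early G1 (27.1 to 31.7), 28.4% in late G1 (26.9 to 29.95), 14.7% in S (13.7 to 15.7) and 18.7% in G2/M (17.7 to 19.8). Distal H3K27ac peaks numbered 14506, 20052, 6796 and 12109, and H3K27me3 was present at 0.627%, 0.713%, 0.250% and 0.239% of them. Among distal H3K27ac peaks, those with H3K4me1 made up 3.02%, 4.63%, 10.9% and 7.88%.

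Bivalent regions, those with H3K4me3 and H3K27me3 in the same fraction, numbered 4721, 4612, 3553 and 4812. They were 21.4% of H3K4me3 regions in early G1 (20.9 to 21.97), 22.4% in late G1 (21.8 to 23.0), 16.03% in S (15.5 to 16.5) and 20.4% in G2/M (19.9 to 20.9). Had the marks fallen on the merged H3K4me3 regions independently, 4312, 4422, 4040 and 4694 regions would have carried both, so the observed numbers were 1.09, 1.04, 0.880 and 1.03 times that. Every one of these regions had H3K4me3 in some fraction, and 20594 to 23618 of the 32799 had it in any given one. The ratios therefore compare the marks only among regions with H3K4me3 in some fraction, and do not show whether the marks meet by chance across the genome. Of the 8055 regions bivalent in any fraction, 1944 (24.1%) were bivalent in all 4 and 3527 in a single one. With the upper part of each list alone, by score, the numbers were 1076, 1719, 1053 and 1691, which places early G1 below late G1. With equal numbers of peaks per fraction they were 4588, 4123, 3423 and 3935, which places early G1 highest. The order of the fractions thus depends on how the lists are cut, apart from S, which was lowest each time.

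Membership of the bivalent set turned over at each step. From early to late G1, 2953 regions stayed bivalent, 1659 entered and 1768 left. Of those entering, 802 already had H3K27me3 in early G1 and 371 already had H3K4me3, and of those leaving, 1165 had lost the H3K4me3 peak alone and 413 the H3K27me3 peak alone. From late G1 to S, 2782 stayed, 771 entered and 1830 left, 843 by loss of H3K4me3 alone and 757 by loss of H3K27me3 alone. From S to G2/M, 2772 stayed, 2040 entered and 781 left. From G2/M to early G1, 2719 stayed, 2002 entered and 2093 left, with 968 of the latter missing from both lists.

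Of the regions bivalent in late G1 and not in early G1, the 8 with the tallest H3K4me3 peaks had H3K4me3 in both fractions. Their relative H3K4me3 height was not unchanged: the late to early G1 log2 ratio ran from 2.04 to 3.37, though they were picked by late G1 height. The tallest was at chromosome 20 from 2779701 to 2782025, with an H3K4me3 height of 896 in late G1, followed by chromosome 6 from 44093826 to 44096625 (814), chromosome 1 from 204041801 to 204045100 (804), chromosome 9 from 103234851 to 103238125 (746) and chromosome 19 from 54481951 to 54484125 (700). The other 3 of these 8 lay at chromosome 4 from 78739351 to 78742025 (634), chromosome 15 from 82335951 to 82339400 (584) and chromosome 19 from 18313801 to 18314925 (567). All 8 except those on chromosome 6 and at chromosome 19 from 18313801 also carried H3K27ac in late G1. Their entry therefore need not mean a newly repressed state. In the opposite set, bivalent in early G1 and not in late G1, the tallest were chromosome 6 from 114177351 to 114181000 (647), chromosome 7 from 75367351 to 75368450 (378), chromosome 5 from 175787526 to 175789150 (372) and chromosome 10 from 124767326 to 124769300 (355). Of these, all but the one on chromosome 7 carried H3K27ac in early G1. Among the 8 tallest of that set, picked by early G1 height, the same log2 ratio ran from -0.36 to 0.39. These regions were picked by H3K4me3 height and do not represent their sets, whose tallies by mark are those above.

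Within each H3K4me3 list, regions bivalent in all fractions were lower than regions with H3K4me3 in all fractions and H3K27me3 in none, and the gap was widest in early G1. The median height of the 1853 bivalent regions was 0.310 times that of the 11470 H3K4me3-only regions in early G1, 0.555 times in late G1, 0.418 times in S and 0.513 times in G2/M. In early G1 the medians were 53.1 and 171, in late G1 40.9 and 73.7, so that the deposited heights of both classes were lower in late G1. With heights taken relative to the library's median over constantly marked regions, 81.7% of bivalent regions stood higher in late G1 than in early G1, with a median log2 ratio of 0.66 (quartiles 0.17 and 1.23). Random lists of H3K4me3-only regions matched on mean height had a median of -0.02, and all 10000 lay below the bivalent value. Against early G1, the difference from matched lists was 0.69 (log2) in late G1, 0.37 in S and 0.59 in G2/M. Against late G1 it was -0.31 in S and -0.06 in G2/M. Without matching on height, the bivalent median was above the H3K4me3-only median on each of 21 chromosomes for late against early G1, by 0.62 to 1.21. The chromosomes share the same libraries, so this cannot tell a property of a library from a difference between fractions. The heights are the authors' own, of unstated scale, so these values compare classes within lists and not amounts of H3K4me3 between fractions. Across the bivalent regions, which are not independent replicates, the late to early G1 height ratios of H3K4me3 and H3K27me3 went together (Spearman rho 0.315).

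**Figure D2:**
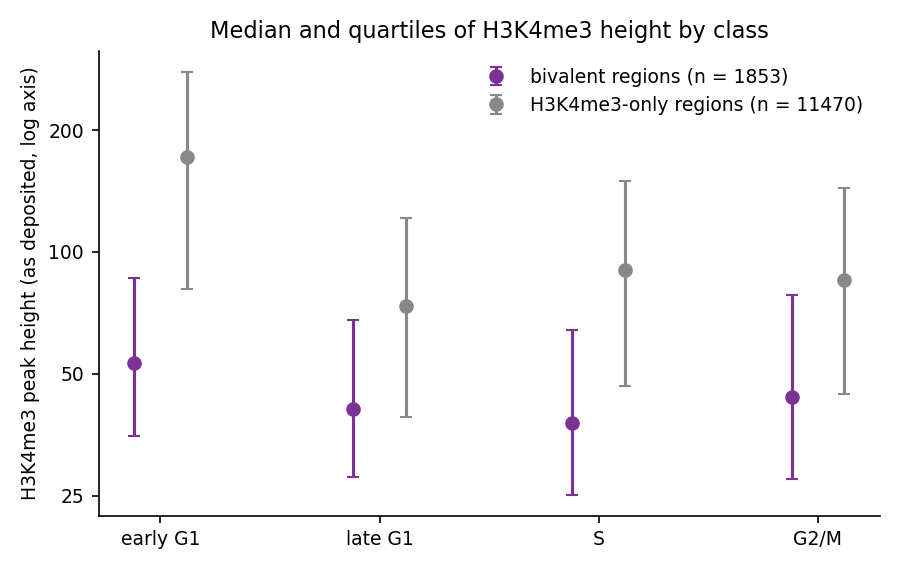
H3K4me3 peak height as deposited (vertical log axis) in each fraction for 1853 regions bivalent in all fractions and 11470 regions with H3K4me3 alone; points are medians and bars run from the lower to the upper quartile. The medians were 53.1 and 171 in early G1 and 40.9 and 73.7 in late G1.

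The regions with the largest relative H3K4me3 height in late against early G1 all carried H3K27me3 in both fractions. They were chromosome 16 from 80837001 to 80838375 (log2 ratio 4.89), chromosome 5 from 77147101 to 77147800 (4.30) and chromosome 12 from 50450776 to 50451525 (4.13). Their early G1 heights were 30.9, 20.8 and 20.96, the latter pair close to that list's 5th percentile of 18.8, which leaves the size of their ratios uncertain. The smallest ratios belonged to regions without H3K27me3 in either fraction, at chromosome 1 from 228643801 to 228645625 (-2.11), chromosome 19 from 20011526 to 20013025 (-2.10) and chromosome 6 from 27598376 to 27599200 (-2.10), with late G1 heights of 26.1, 33.4 and 21.4 against a 5th percentile of 15.98.

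The GATA6 locus carried H3K4me3 and H3K27me3 in every fraction. The gene lies between MIB1 and CTAGE1 in the order of protein-coding genes. Within 25 kb of the 4C site with the most reads, at chromosome 18 position 19758344, H3K27me3 covered 19.2, 19.5, 17.7 and 19.0 kb. The longest late G1 peak ran from 19741651 to 19760450. A short H3K4me3 peak lay inside that domain, from 19748926 to 19749175 in early G1, 19749001 to 19749400 in late G1, 19748851 to 19749175 in S and 19748926 to 19749400 in G2/M. Early G1 had another of 125 bp, from 19749851 to 19749975. Within its list, the taller peak stood above 20.0%, 51.8%, 33.3% and 49.7% of H3K4me3 peaks by height. The H3K27me3 maximum stood above 98.8%, 97.9%, 96.4% and 97.8% of its list. No H3K27ac or H3K4me1 peak was listed there in any fraction.

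The SOX17 locus was covered by H3K27me3 in every fraction, with H3K4me3 listed in G2/M alone. The gene lies after MRPL15 in the same order. Around chromosome 8 position 55373264, H3K27me3 covered 22.3, 22.6, 20.3 and 21.4 kb, and the longest early G1 peak ran from 55363476 to 55385225. The single H3K4me3 peak, from 55382776 to 55382875 in G2/M, was 100 bp long and stood above 3.22% of its list, near the lowest heights listed. No H3K27ac or H3K4me1 peak was listed there.

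**Figure D3:**
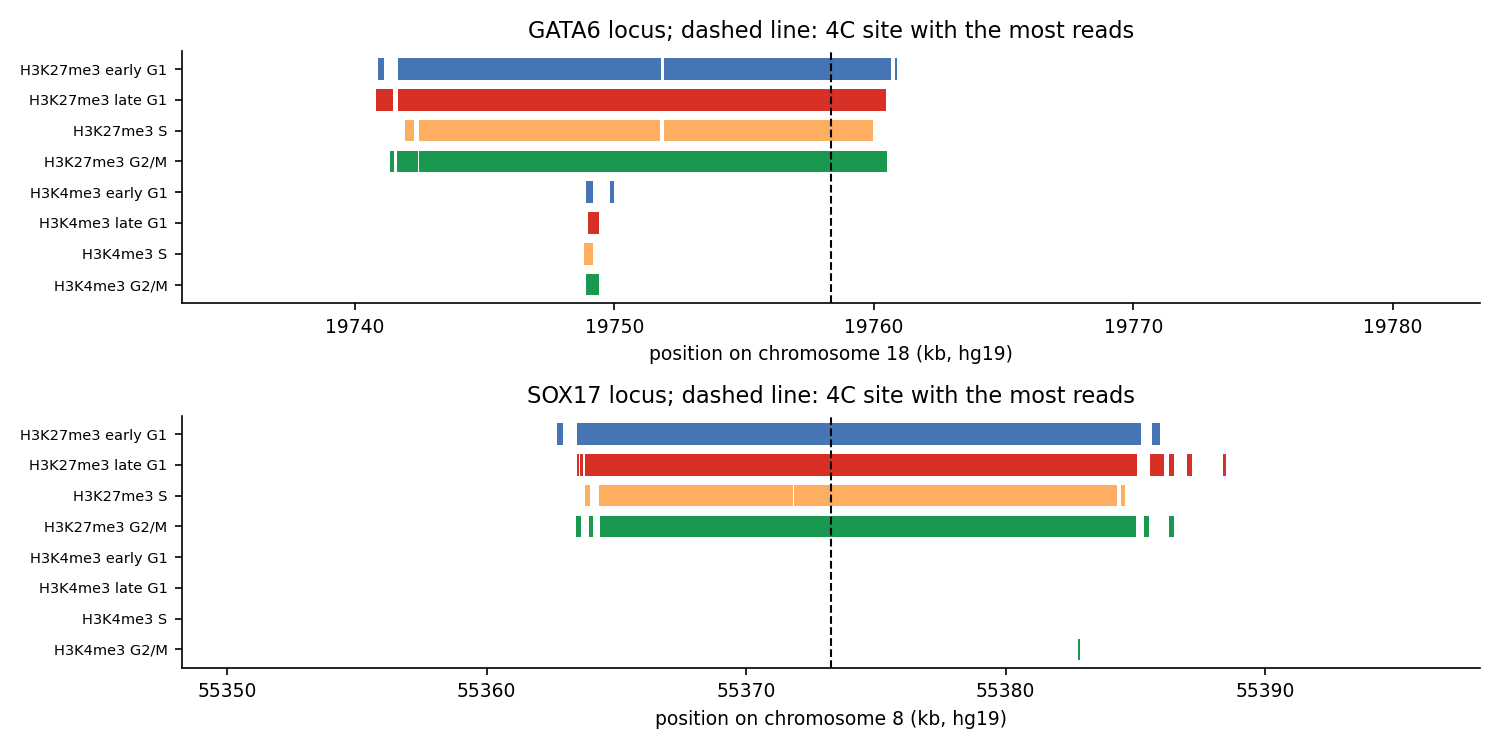
Listed H3K27me3 and H3K4me3 peaks (bars, to scale) within 25 kb of the 4C site with the most reads (dashed line) at GATA6 and SOX17; the horizontal axis is position in kb and each line is 1 library. H3K4me3 is present at GATA6 in all 4 fractions, and at SOX17 as a single 100 bp peak in G2/M.

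From the GATA6 viewpoint, a smaller share of the reads on the same chromosome lay far from the viewpoint in S and G2/M than in early G1. Leaving out 10 kb either side, 30.9%, 27.7%, 24.4% and 25.6% of reads on chromosome 18 lay more than 1 Mb away, and 12.3%, 10.9%, 8.25% and 8.01% more than 10 Mb away. Reads on other chromosomes made up 31.5%, 32.3%, 26.7% and 24.98% of all reads outside those 10 kb. With 5709178 to 11081301 reads behind each cis share, the counting intervals were narrow, from 12.2 to 12.3% over 10 Mb in early G1 and from 7.99 to 8.03% in G2/M. Over 140 windows of 50 kb within 5 Mb, which are not independent replicates, rank correlations of reads between pairs of fractions lay between 0.988 and 0.995. The decay of reads with distance was not taken off, so these values do not show whether contacts differed. The window with the most reads in early G1, late G1 and S lay at chromosome 18 from 20000001 to 20050000, 267 kb from the viewpoint, with 6.09%, 6.29%, 6.57% and 6.07% of cis reads. In G2/M the first place went to the window that holds the viewpoint, from 19750001 to 19800000, with 6.15%, and this window was among the first 5 in every fraction. The others among the first 5 were 19950001 to 20000000 and 19700001 to 19750000 in all fractions, 20250001 to 20300000 in early and late G1, and 19900001 to 19950000 in S and G2/M. Windows were ranked by summed reads, not by reads per restriction site. The window 267 kb away held 26 counted sites and the viewpoint's own 10, so the ranks depend on site density too.

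From the SOX17 viewpoint the order of the fractions was similar. Reads more than 1 Mb away made up 43.8%, 41.2%, 36.8% and 36.8% of cis reads, and reads more than 10 Mb away 19.2%, 17.6%, 14.9% and 13.3%. Reads on other chromosomes made up 25.4%, 26.2%, 22.2% and 20.4% of all reads outside 10 kb of the viewpoint. Counting each occupied site once, the G2/M minus early G1 difference on other chromosomes was -0.872 percentage points for SOX17 and -0.540 for GATA6, against -4.96 and -6.49 for reads. Over 1 Mb the difference was -1.93 points for SOX17 and -1.56 for GATA6 by sites, against -7.07 and -5.26 by reads. The difference over 10 Mb was -10.4 points for SOX17 and -7.13 for GATA6 by sites, against -5.89 and -4.26 by reads. The window with the most reads lay at chromosome 8 from 55050001 to 55100000 in early G1, late G1 and G2/M, 298 kb from the viewpoint, with 6.36%, 6.88%, 7.20% and 7.22% of cis reads. In S it was the viewpoint's own window, from 55350001 to 55400000, with 7.24%. The remaining places among the first 5 went in every fraction to 55300001 to 55350000, 55100001 to 55150000 and 55400001 to 55450000. The window 298 kb away held 14 counted sites and the viewpoint's own 10, and site number was not taken into account. Rank correlations between pairs of fractions lay between 0.965 and 0.989 across 201 windows, again with the decay included. The number of cis sites with any read was lowest in G2/M, at 11280, 11311, 12624 and 8347 for GATA6 and 19810, 16698, 21378 and 12027 for SOX17.

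**Figure D4:**
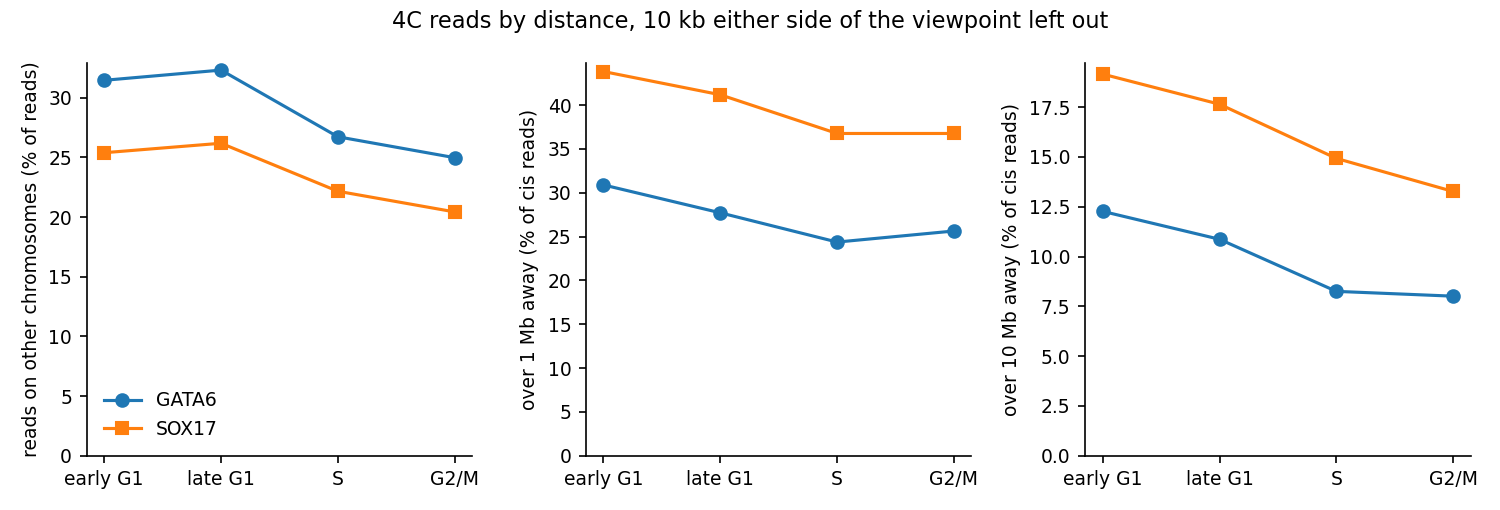
Share of 4C reads (vertical axes, percent) on other chromosomes, over 1 Mb away and over 10 Mb away on the same chromosome for the GATA6 and SOX17 viewpoints in the 4 fractions, 1 library per point. The share over 10 Mb was 12.3% in early G1 and 8.01% in G2/M for GATA6, and 19.2% and 13.3% for SOX17.

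Among the first 20 contact windows of each fraction, the number with an H3K4me3 peak lay between percentiles 97.8 and 99.96 of windows matched on distance for SOX17 and between 4.74 and 9.88 for GATA6, and with 50 windows it lay between 67.2 and 94.97 for SOX17 and between 27.8 and 82.2 for GATA6. Among the 20 windows with the most SOX17 reads, 5, 5, 4 and 5 held an H3K4me3 peak of the same fraction, at percentiles 99.7, 99.96, 99.4 and 97.8 of 10000 matched sets. H3K27me3 was present in 4, 4, 3 and 3 of them, at percentiles 99.3, 98.4, 95.8 and 96.2. Among the 20 GATA6 windows, 2, 2, 2 and 3 held H3K4me3, at percentiles 4.74, 4.83, 4.90 and 9.88, and H3K27me3 was present in 6, 5, 5 and 6, at percentiles 50.6, 50.4, 62.8 and 73.2. With the first 50 windows in place of 20, the SOX17 percentiles for H3K4me3 were 67.2, 94.97, 80.7 and 82.8 and those of GATA6 41.2, 27.8, 56.7 and 82.2. For H3K27me3 they were 74.7, 66.1, 63.2 and 71.2 for SOX17 and 48.8, 35.7, 16.8 and 46.97 for GATA6. H3K27ac was present in 2, 1, 0 and 0 of the 20 GATA6 windows, at percentiles 1.01, 3.64, 29.7 and 5.85, and with 50 windows these became 94.3, 93.9, 81.3 and 67.04. It was present in 4, 5, 0 and 1 of the 20 SOX17 windows, at percentiles 95.7, 92.5, 29.7 and 47.1, and with 50 windows these became 63.9, 99.1, 96.2 and 26.3. H3K4me1 was present in at most 1 of the 20 windows of either viewpoint. All 10 windows within 250 kb of each viewpoint were among the 20, so the matching acts on the more distant ones.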

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

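The tests by matched lists, shared coverage, H3K27ac score, occupied sites and reads from 1 to 10 Mb were chosen only after the result was seen, and the removal of regions with H3K27me3 and H3K27ac together after the data were seen.

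Peak numbers of the 4 marks moved in different directions between fractions, and the difference was not tested. From late G1 to S the number of peaks changed 1.01-fold for H3K4me3, 0.631-fold for H3K27me3, 0.316-fold for H3K27ac and 1.56-fold for H3K4me1. From S to G2/M the changes were 1.11, 1.32, 1.90 and 0.980-fold in the same order of marks. From G2/M to early G1 they were 0.862, 0.897, 1.55 and 0.305-fold. Occupied sites on the viewpoint's own chromosome, late over early G1, went 1.003-fold for GATA6 and 0.843-fold for SOX17, on opposite sides of no change and untested as well.

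Each viewpoint's libraries also held reads at the other viewpoint, which the comparisons above count only as part of the share on other chromosomes. Within 10 kb of the SOX17 viewpoint the GATA6 libraries held 228, 236, 79 and 16 reads in the order early G1, late G1, S and G2/M, more than 96.1%, 96.9%, 95.3% and 89.4% of windows of that size on chromosome 8, the G2/M value being 0.631 times the mean window. Within 10 kb of the GATA6 viewpoint the SOX17 libraries held 558, 386, 237 and 958 reads, more than 99.9%, 99.5%, 99.4% and 99.8% of windows of that size on chromosome 18.

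The wider gap between bivalent and H3K4me3-only regions in early G1 is the first pattern weighed. A trend with height alone is argued against by the matched lists, since the bivalent median for late against early G1 stood at percentile 100 of them. Regions that carry peaks whatever the mark stay open: without those holding H3K27me3 and H3K27ac together the difference from matched lists was 0.67 (log2) against 0.69, but this took out 170 of 1853 regions, and removing the 170 highest would have left 0.58, so the test could not have come out otherwise. Coverage differences per region shared by libraries of one fraction stay open as well: across the 1853 bivalent regions, the late to early G1 ratios of H3K4me3 and H3K27me3 height went together with a Spearman rho of 0.315, and the median H3K4me3 shift was 0.44 where the H3K27me3 ratio was lowest and 1.05 where it was highest. For S against early G1, rho was 0.327 and these shifts were 0.11 and 0.66. For G2/M against early G1, rho was 0.355 and they were 0.19 and 0.96. Such a link was not particular to bivalent regions. At 3794 H3K4me3-only regions with H3K27ac in both G1 fractions, the late to early G1 height ratios of those marks also went together (rho 0.294). With 1 library per fraction, a cell cycle difference and a property of the early G1 library both remain possible, and neither was tested.

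The short H3K27ac list in S phase is the second. A loss of peaks whatever their strength is argued against as the whole cause: the stronger part of the late G1 list by score was found in S 0.584 times as often as in early G1 (39.0% against 66.8%) and the weaker part 0.221 times as often (7.14% against 32.3%), a ratio of 0.378 (0.356 to 0.399, resampling peaks) where such a loss alone predicts a ratio near 1. A weaker library that loses peaks by strength alone predicts equal rates at equal score, but matched late G1 peaks near H3K4me3 were found in S less often than those away from it (21.7% against 27.8%), a difference of -6.18 points (-6.99 to -5.37). This passes the 5-point bound by little, and the score of 1 library need not measure strength equally in both places. Depth may still account for part of the shortfall, and a cell cycle difference in acetylation stays open and untested.

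For the third, the lower share of distant 4C reads in G2/M, random ligation is argued against, since taking off the reads per site seen on other chromosomes left 95.4% of the fall over 10 Mb for GATA6 and 96.1% for SOX17. Reads next to the viewpoint are argued against because reads over 10 Mb relative to those from 1 to 10 Mb were also lower in G2/M, 0.690 times the early G1 ratio for GATA6 and 0.727 times for SOX17. Fewer amplified sites cannot be told apart from a difference between fractions, because G2/M had both the lowest share and the fewest occupied cis sites, 0.740 times those of early G1 for GATA6 and 0.607 times for SOX17. Against them, the 4 fractions did not rank alike by sites and by share at either viewpoint, S having more sites and a lower share than early G1, and an earlier rank correlation test that excluded them was replaced after its result was seen because 4 libraries are too few, while a difference in chromosome folding stays open and untested.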

How the results depend on the processing

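Scores in place of heights and the removal of regions with H3K27me3 and H3K27ac together were chosen after the data were seen. Of 152 alternative values for 63 results, 90 stayed within the interval or the 1.5-fold limit for counts and 62 moved. Of the 90, 3 were heights as deposited, which could not differ because a library's constant cancels, and 31 were shares of contact windows with wide intervals from 20 windows; the share of GATA6 windows with H3K27ac in late G1 moved from 5% to 28% with 50 windows. Among the 9 results that are differences, 0 of the 45 alternatives that could move changed sign, though removing the regions with H3K27me3 and H3K27ac together took out too few to change it. Other alternatives were weak checks too. Scores and heights ranked H3K4me3 peaks almost alike (Spearman rho -0.982 to -0.991). Leaving out the tallest site moved 4C differences little, as from -4.26 to -4.30 for GATA6 over 10 Mb. The absence of sign changes there says little about robustness. Where values moved, the cause was not tested beyond the alternative's own construction. Planned promoter and gene-list alternatives were not run as written for want of an hg19 annotation; their window sizes and filters were applied to merged H3K4me3 regions. No paired analysis was possible because each group had 1 library. ChIP depth is unknown here and limits every list length.

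For late G1 peaks shared with early G1, the upper part of each list gave 84.6% (H3K4me3), 61.8% (H3K27me3) and 51.3% (H3K27ac), equal numbers 82.3%, 64.0%, 51.4% and 4.37% (H3K4me1), peaks of at least 500 bp 91.6%, 71.7%, 60.7% and 11.8%, and coverage of at least 50% of the peak 76.8%, 42.1%, 39.4% and 2.02%. Without regions holding H3K27me3 and H3K27ac together, H3K27me3 gave 50.9%.

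With the upper part of each list, bivalent regions numbered 1076, 1719, 1053 and 1691, distal H3K27ac peaks 7239, 10443, 3532 and 6461, and distal H3K4me1 peaks 802, 1739, 2710 and 2739, from early G1 to G2/M.

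The bivalent difference from matched lists against early G1 (late G1, S, G2/M; log2) was 0.85, 0.56 and 0.76 with the upper part of the lists, 0.59, 0.29 and 0.47 with H3K27me3 within 2500 bp, 0.63 and 0.33 for late G1 and S within 500 bp, and as a rank between 0 and 1 it was 0.143, 0.0669 and 0.107.

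For 4C, G2/M minus early G1 in percentage points for GATA6 over 1 Mb, over 10 Mb and on other chromosomes was -5.94, -4.32 and -7.06 with 2 kb left out, -5.36, -4.56 and -6.45 with 50 kb left out, and -1.56, -7.13 and -0.540 with sites counted once; without the tallest site the value over 10 Mb was -4.30. For SOX17, over 1 Mb and on other chromosomes it was -7.24 and -5.06 with 2 kb left out; over 1 Mb and 10 Mb -7.20 and -6.33 with 50 kb; -1.93, -10.4 and -0.872 by sites; and -5.95 over 10 Mb without the tallest site. The early G1 to G2/M rank correlation was 0.973 (GATA6) and 0.956 (SOX17) in 20 kb windows, and 0.994 and 0.979 in 100 kb windows.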

Other observations

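The region named here and the correlation test below were chosen after their results were seen. The tallest H3K4me3 peak of late G1, at chromosome 15 from 66994701 to 67000800, had a height of 1349, and the same place was listed for H3K4me3 and H3K27me3 in all 4 fractions. Its H3K27me3 height in the late G1 list was 882. In late G1, S and G2/M the deposited H3K4me3 height there was 5.67, 1.80 and 5.56 times that of early G1. The H3K27me3 height was 2.92, 1.44 and 4.03 times that of early G1, so both marks moved in the same direction at this place. No H3K27ac peak was listed there, and H3K4me1 was listed in G2/M alone.

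H3K4me3 peaks that overlapped both H3K27me3 and H3K27ac numbered 245, 211, 77 and 135 from early G1 to G2/M, and 4, 12, 17 and 32 of them overlapped H3K4me1 as well. The 655 merged regions where H3K27me3 and H3K27ac peaks overlapped in any fraction held 1.62% to 1.84% of H3K4me3 peaks. Across 3794 H3K4me3-only regions with H3K27ac in both G1 fractions, the late to early G1 height ratios of those marks had a Spearman rho of 0.294; regions are not independent replicates.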
